A study of Mus musculus with 6 samples.

How the data were processed

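RNA from the limb bones of mouse pups 1 day after birth was measured by RNA-seq in 6 libraries, 3 from wild type pups and 3 from pups labelled as a conditional knockout of Hdac3 with Prx1 (Hdac3 CKO). Hdac3 encodes a histone deacetylase. The Prx1 (Prrx1) enhancer is widely used to drive Cre recombinase in the mesenchyme of the limb bud, which gives rise to bone, cartilage and tendon but not to blood cells or muscle fibres. Per the labels' protocols, bones of hindlimbs and forelimbs were cleaned of soft tissue, lysed in TRIzol and made into libraries with a TruSeq v2 mRNA kit. The labels give the genotype of each library and no shared replicate numbers, so replicates were numbered within each genotype in the order of their records. The labels do not say whether each library came from a separate animal or litter. The p-values therefore measure only the spread between these libraries, which may be technical in part.

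The authors deposited whole-number read counts per gene for each library. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Subread and featureCounts were used with the mm10 build. The strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies, may therefore be shared or lost. The authors also deposited RPKM values, which scale reads by gene length and library total. Those values were checked against the counts and used the gene length in the deposited table plus 1 base, with library totals larger than the summed gene counts, of which 72.1% to 87.0% lay in genes. The count table held 43346 genes, and 12478 had no count in any library. Coordinates are those of the deposited table on mm10. Of its gene identifiers, 98.0% were found in the GENCODE M21 annotation of the same assembly, which was used for gene types, GC content and exon overlaps.

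Total counts per library ranged from 43389262 to 50927978. Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3), after the edgeR filter on low counts left 20210 genes, which held 99.9% of all counts. The genotypes were compared with edgeR's quasi-likelihood test with robust moderation and no covariate, with 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method. A gene was said to have risen or fallen at an adjusted p under 0.05. Values per library are TMM-normalised CPM, and errors of log2 fold changes are standard errors from the fit. Gene lists were compared with the other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 34 lists. A list needed at least 4 measured members. Camera with an estimated correlation and fry were run as alternatives. The p of fry tests whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes.

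The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named 8 core genes (Hdac3, Runx2, Sp7, Col1a1, Sox9, Col2a1, Col10a1 and Mmp13). It also named the 8 genes with the largest fold change in each direction that passed the test, had a mean count of at least 10 and did not overlap between the genotypes. Symbols of predicted genes, pseudogenes and sex-linked genes were left out of this ranking, which removed 22 genes. Of each list it named the 2 members with the smallest p, or 4 where camera called the list. The lists covered the HDAC3 corepressor complex, other histone deacetylases, bone and cartilage cell types, osteoclasts, matrix proteases and inhibitors, limb transcription factors and hindlimb identity. They also covered signalling pathways, metabolism, stress, the cell cycle, the circadian clock, blood and immune cells, and other tissues of the limb. A list of sex-linked genes gave values only. Some genes that the rule selects are not reported here.

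The procedure was tested on simulated counts for the comparison of Hdac3 CKO with wild type, run on 19863 genes. It called 51.0% of genes changed 2-fold and 92.7% of genes changed 4-fold, 6.76% of its calls were unchanged genes, and 0 had the wrong direction. A shifted list had an adjusted p of 1.8e-13 in camera with the preset correlation, 0.12 with an estimated correlation and 0.020 in fry. Of 33 unshifted lists, camera called 0 with either correlation and fry called 1. The simulated genes varied independently of each other, while the estimated correlation in the measured lists reached 0.88 for neutrophil genes. The simulation therefore does not show how often camera with the preset correlation calls unshifted lists whose genes vary together.

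The alternatives were other scaling factors, other filters on low counts, other estimates of the spread, DESeq2 1.42.0, limma-voom, limma with sample weights, and limma on log2 RPKM with a pseudocount of 1 or 0.1. Further alternatives were a minimum fold change of 1.5, covariates for muscle, erythroid, neutrophil, Y-linked and limb markers, leaving out muscle, blood and sex-linked genes, and leaving out each library in turn. A covariate leaves 3 residual degrees of freedom. A cartilage covariate, leaving out both libraries rich in cartilage transcripts, leaving out loci of ribosomal RNA type, and offsets for GC content and length were added after seeing the data. Pairs of libraries of 1 genotype differed by a mean chi-square per gene of 47.4 to 132, so none of these 6 pairs agreed within sampling noise.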

Results

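Limb bone transcriptomes of mouse pups were compared between 3 wild type and 3 Hdac3 CKO libraries to ask how the loss of Hdac3 in limb mesenchyme changes gene expression in forming bone. The total count was 50927978, 47392678 and 46156691 in wild type replicates 1, 2 and 3, and 46926855, 43389262 and 45119142 in Hdac3 CKO replicates 1, 2 and 3.

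Hdac3, the targeted gene (ENSMUSG00000024454, chromosome 18, 37935844 to 37954988), stood at 48.4, 47.4 and 50.3 CPM in the wild type libraries and at 31.8, 29.4 and 28.3 CPM in the Hdac3 CKO libraries. The mean was 48.7 ± 1.4 CPM (SD, n = 3) in wild type and 29.8 ± 1.8 CPM (SD, n = 3) in Hdac3 CKO. Hdac3 fell to 0.613 of its wild type level, a log2 fold change of -0.71 ± 0.12 (SE), with an adjusted p of 0.027 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 3 Hdac3 CKO libraries lay below all 3 wild type libraries, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The adjusted p was 0.126 without wild type replicate 1, 0.118 without wild type replicate 2, 0.106 without wild type replicate 3, 0.068 without Hdac3 CKO replicate 2 and 0.108 without Hdac3 CKO replicate 3. In the HDAC3 corepressor complex list, 0 of 6 members rose and 1 fell, which was Hdac3. Adjusted over the list alone, 1 rose and 1 fell. Its median of 0.04, its mean of -0.01 and camera's direction, which was higher, differed in sign. Of 10 other histone deacetylases, 0 rose and 0 fell, also adjusted over the list alone. Hdac2 stood at -0.31 and Hdac1 at -0.30, while 4 of the 10 stood above 0, and the list median was -0.095. Fry gave this list an adjusted p of 0.027 in the lower direction, while camera gave 0.55, or 0.64 with an estimated correlation.

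**Figure D1:**
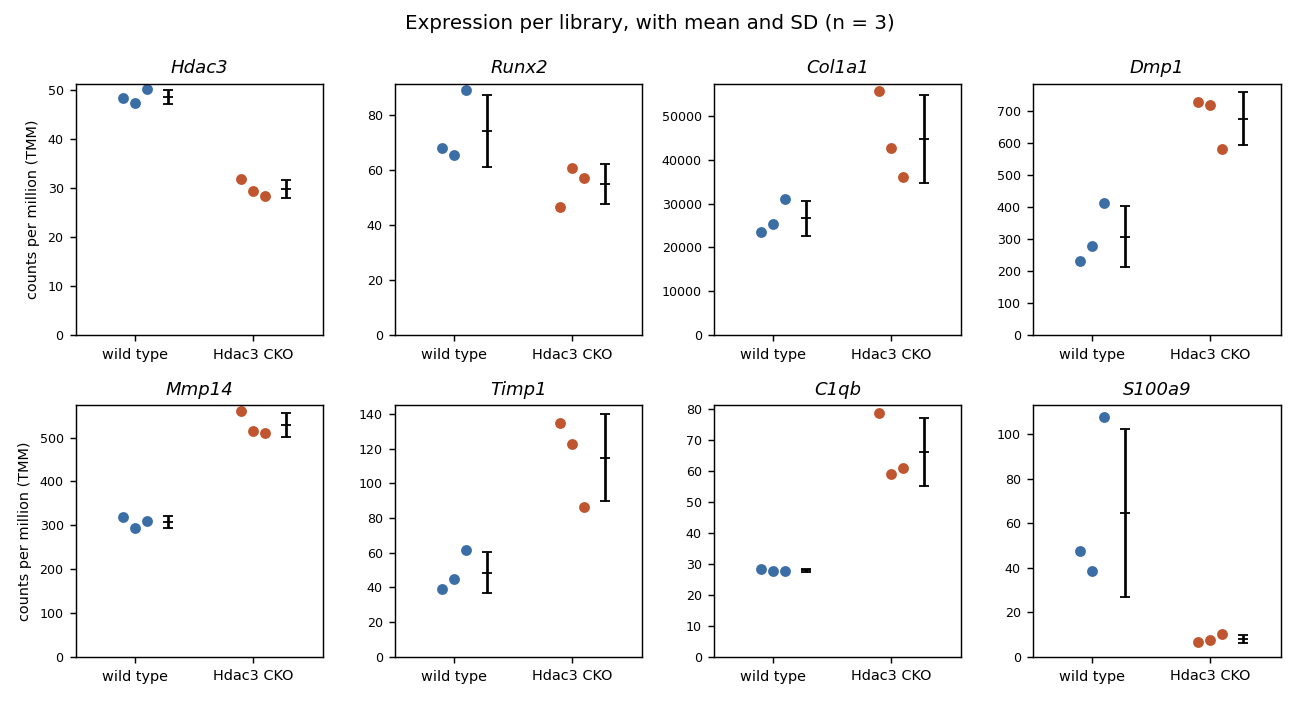
TMM-normalised CPM of 8 genes in each library (points), by genotype, with the mean and SD (n = 3) as bars and every vertical axis starting at 0. Hdac3 lay between 47.4 and 50.3 CPM in wild type and between 28.3 and 31.8 CPM in Hdac3 CKO, while Runx2 and Col1a1 did not pass the test.

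Across the transcriptome, 142 genes rose and 96 fell in Hdac3 CKO bones, together 238 of 20210 genes tested, and 219 of them were protein-coding. Among the genes that the naming rule ranked, the largest rise was that of Tmem59l (chromosome 8, 70483876 to 70487358), from 0.064 to 2.28 CPM, a log2 fold change of 5.08 ± 0.38. Mmp20, which rose but had too low a mean count for the ranking, had 0 counts in wild type and 35 in Hdac3 CKO. Fgf21, a hormone of the fasting response, rose by 3.51 ± 0.70, from 0.039 to 0.473 CPM. Also among the largest rises were the protease inhibitor Serpinb2 (2.91), the stromelysin Mmp10 (2.85), Chac1 (2.74), which encodes a glutathione-degrading enzyme, and Irs3 (2.62). Calm5 (2.83) and AC132239.1 (2.72) overlap on chromosome 13, so their counts are not independent. The largest fall among the ranked genes was that of Grpr, the gastrin-releasing peptide receptor, at -4.69 ± 0.86. Grpr had 105 counts in wild type and 3 in Hdac3 CKO, a ratio of 32.8 with a 95% exact counting interval of 10.9 to 162. That interval leaves out the spread between libraries, and the wild type libraries held 54, 30 and 21 counts. The other large falls included genes of granulocytes, Retnlg (-3.55), Olfm4 (-3.37) and S100a9 (-3.00), with Aqp9 at -3.02. BC117090 (-3.15) and Stfa2l1 (-3.08) belong to a stefin A cluster on chromosome 16 whose members are near-identical, so their separate values are uncertain.

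All 238 genes had values that did not overlap between the genotypes, as had 22.5% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 3031 genes. The count was 23 without wild type replicate 1, 35 without wild type replicate 2, 105 without wild type replicate 3 and 46 without Hdac3 CKO replicate 3, and DESeq2 called 829. Whichever library was left out, all 238 genes kept their direction and an unadjusted p under 0.05 in edgeR, though selected on the same libraries. With library totals in place of TMM factors the median of all tested genes shifted to -0.18, and the share of higher genes among the calls was 32.6% in place of 59.7%.

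The main osteoblast genes did not pass the test. Runx2, the master transcription factor of osteoblasts, stood at -0.44 ± 0.16, and Sp7, which acts after it, at 0.38 ± 0.18. Col1a1, the main bone collagen, averaged 26627 CPM in wild type and 44768 CPM in Hdac3 CKO, at 0.75 ± 0.23 with an adjusted p of 0.18 in edgeR's quasi-likelihood test. In the osteoblast and bone matrix list, 0 of 15 members rose or fell over all genes, and 4 rose adjusted over the list alone, among them Ibsp (1.21) and Sparc (0.65). Camera gave this list an adjusted p of 0.073, and its median of 0.18 was -0.0080 with GC and length offsets. It was called higher without wild type replicate 3 (0.0011), without Hdac3 CKO replicate 3 (0.035), without both (7.9e-04), with no filter on low counts (0.015) and with the Y-linked (0.019) and erythroid (0.036) covariates, each an adjusted p in camera. In the osteocyte list 1 of 6 members rose, also adjusted over the list alone. It was Dmp1, a matrix phosphoprotein of osteocytes, at 1.14 ± 0.21, while Mepe stood at -0.79, and the list had an adjusted p of 0.57 in camera.

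Col2a1, the main cartilage collagen, varied more within the genotypes than between them. It stood at 882, 784 and 5212 CPM in wild type and at 896, 453 and 11502 CPM in Hdac3 CKO, so its log2 fold change of 0.90 had a standard error of 1.58. Sox9, the transcription factor of chondrocytes, stood at -0.41 ± 0.36, and Col10a1, a collagen of hypertrophic cartilage, at 0.54 ± 0.77. Without Hdac3 CKO replicate 3, Col2a1 stood at -1.76 and Col10a1 at -0.41. Of 16 genes of the cartilage matrix and chondrocyte list 0 rose or fell, over all genes or adjusted over the list alone, with Sox5 at -1.26 and Col11a1 at 0.70, which were among 3 of the 16 whose values did not overlap between the genotypes, where chance gives 10% and all tested genes gave 22.5%. Its median of 0.31 and mean of 0.19 were above 0 and camera's direction was lower, with an adjusted p of 0.64. Camera called it lower without Hdac3 CKO replicate 3 (2.4e-04), without both cartilage-rich libraries (5.5e-04) and with the Y-linked covariate (0.024), and higher with the erythroid covariate (8.3e-40). These calls used the preset correlation, while the estimated correlation of this list was 0.78, with an adjusted p of 0.94 in camera without a covariate. The erythroid marker mean did not overlap between the genotypes, so the value with that covariate carries little weight. Of 9 hypertrophic chondrocyte genes 0 rose or fell over all genes and 1 rose adjusted over the list alone, Ibsp. Mmp13, the collagenase of hypertrophic cartilage and bone, stood at 0.69 ± 0.27, and camera gave the list an adjusted p of 0.059. It was called higher without wild type replicate 3 (0.0027), without Hdac3 CKO replicate 1 (0.0044), without both cartilage-rich libraries (0.029), with no filter (0.021), with GC and length offsets (0.011) and with the muscle (0.0037), cartilage (0.0030) and erythroid (1.4e-07) covariates.

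Of 14 matrix proteases and inhibitors 5 rose, 0 fell and 9 did not pass, and 10 rose adjusted over the list alone. Mmp14, a membrane collagenase, rose by 0.78 ± 0.13, Mmp10 by 2.85 ± 0.48, and the metalloproteinase inhibitors Timp1 and Timp2 by 1.24 ± 0.21 and 0.75 ± 0.14. Camera gave an adjusted p of 4.1e-08 with the preset correlation and an adjusted p = 0.075 with an estimated correlation, and fry gave 0.0056. The number of matrix proteases and inhibitors that rose was 0 without wild type replicate 1 or 2, 3 without wild type replicate 3, 2 without Hdac3 CKO replicate 2 and 1 without Hdac3 CKO replicate 3. Of 12 osteoclast genes 0 rose or fell over all genes and 6 rose adjusted over the list alone. Dcstamp (0.88) and Ocstamp (1.02), both needed for osteoclast fusion, were higher on average, as were Mmp9 (0.93) and Tnfrsf11a (0.59), the receptor of the osteoclast factor RANKL. Without wild type replicate 3 the number that rose over all genes was 3. Camera called this list higher with an adjusted p of 2.3e-05, and adjusted p = 0.51 with an estimated correlation.

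**Figure D2:**
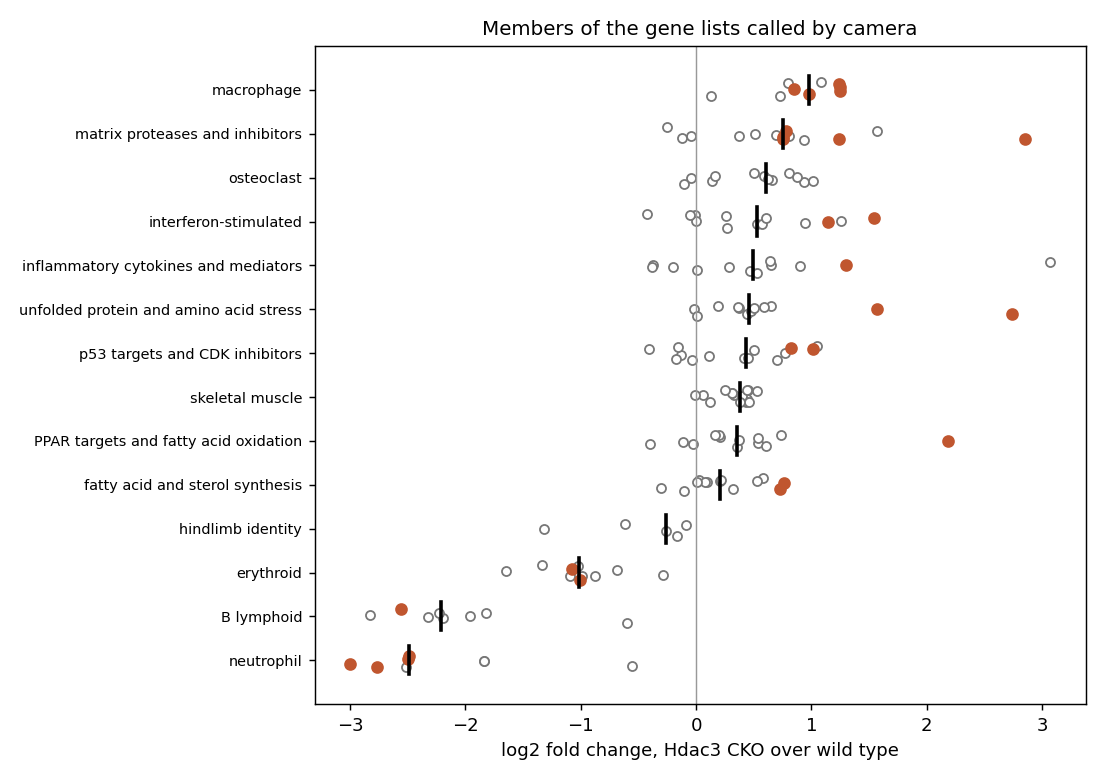
Log2 fold change of Hdac3 CKO over wild type (horizontal axis) of each measured member (points) of the 14 gene lists that camera called with the preset correlation. Filled points passed the test over all genes and black bars are list medians, which ran from -2.49 for neutrophil markers to 0.98 for macrophage markers.

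Camera with the preset correlation called the macrophage list higher and the neutrophil, B lymphoid and erythroid lists lower, and called none of these 4 with an estimated correlation. Of 9 macrophage genes 5 rose and 0 fell, and 8 rose adjusted over the list alone. The complement genes C1qa (1.25), C1qb (1.24) and C1qc (1.24) and the surface marker Emr1 (0.98) were the members with the smallest p. The adjusted p in camera was 4.0e-10, with adjusted p = 0.075 with an estimated correlation, and fry gave 0.0056. The number that rose was 1 without wild type replicate 1, 0 without wild type replicate 2, and 3 without Hdac3 CKO replicate 2 or 3. Of 8 neutrophil genes 4 fell and 0 rose, and 7 fell adjusted over the list alone. They were S100a9 (-3.00), S100a8 (-2.76), Ngp (-2.49) and Camp (-2.49), and camera gave an adjusted p of 2.6e-07, adjusted p = 0.41 with an estimated correlation. The number that fell was 1 without wild type replicate 1, 2 without wild type replicate 2, 0 without Hdac3 CKO replicate 1 or 2, and 1 without Hdac3 CKO replicate 3. Of 8 B lymphoid genes 1 fell and 0 rose, and 7 fell adjusted over the list alone. It was the recombinase Rag1 (-2.56), with Igll1 at -2.82 and Vpreb3 at -2.33. The list had an adjusted p of 1.0e-06 in camera, adjusted p = 0.41 with an estimated correlation. Of 10 erythroid genes 2 fell and 0 rose, and 8 fell adjusted over the list alone. They were Alas2 (-1.01), the first enzyme of red cell heme synthesis, and Hbb-bs (-1.07), with Hba-a1 at -0.99 and Hbb-bt at -1.09. Globin genes have near-identical copies, so their separate values are uncertain. In camera the adjusted p was 4.1e-07, adjusted p = 0.22 with an estimated correlation. Erythroid genes that fell numbered 2 without wild type replicate 1 and 0 without any other library, and B lymphoid genes numbered 1 without wild type replicate 2 and 0 without any other.

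The interferon and inflammatory lists were called higher by camera with the preset correlation and not with an estimated one. Of 13 interferon-stimulated genes 2 rose and 0 fell, and 5 rose adjusted over the list alone. They were the chemokine Cxcl10 (1.54) and Oas1a (1.14), with Mx1 at 1.26 and Ifit3 at 0.94, and camera gave an adjusted p of 0.0022, adjusted p = 0.51 with an estimated correlation. Of 12 inflammatory cytokines and mediators 1 rose and 0 fell, and 2 rose adjusted over the list alone. It was Ptgs2 (1.30), the inducible enzyme of prostaglandin synthesis, with Saa3 at 3.07, Ccl2 at 0.65 and Ccl7 at 0.64. Camera gave this list an adjusted p of 0.013, adjusted p = 0.51 with an estimated correlation. That call was lost without wild type replicate 2 (0.058) or Hdac3 CKO replicate 2 (0.076). In the interferon list 1 gene rose without Hdac3 CKO replicate 2 and 0 without any other library, and in the inflammatory list 1 rose without Hdac3 CKO replicate 1 or 2 and 0 without any other.

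Camera with the preset correlation called both stress lists higher, that of unfolded protein and amino acid stress and that of p53 targets, and neither with an estimated correlation. Of 12 genes of the unfolded protein and amino acid stress list 2 rose and 0 fell, and 9 rose adjusted over the list alone. They were Chac1 (2.74) and Trib3 (1.57), both targets of the stress factor ATF4, with Ddit3 at 0.59 and Sdf2l1 at 0.65. Camera gave an adjusted p of 7.8e-07, adjusted p = 0.15 with an estimated correlation, and fry gave 0.0069. Of 14 p53 targets and CDK inhibitors 2 rose and 0 fell, and adjusted over the list alone 7 rose and 1 fell. They were Cdkn1a (1.01), which encodes the cell cycle inhibitor p21, and Phlda3 (0.82), with Sesn2 at 1.05 and Eda2r at 0.77. Camera gave an adjusted p of 0.0012, adjusted p = 0.15 with an estimated correlation, and fry gave 0.024. Stress genes that rose numbered 2 without Hdac3 CKO replicate 2, 1 without wild type replicate 3 and 0 without any other library. In the p53 list the number was 3 without Hdac3 CKO replicate 1, 2 without Hdac3 CKO replicate 2, 1 without wild type replicate 3 and 0 without any other. Of 19 cell cycle genes 0 rose or fell, also adjusted over the list alone, with Bub1 at -0.74, Ccna2 at -0.31 and an adjusted p of 0.30 in camera, which called it lower without Hdac3 CKO replicate 1 (0.0075) and with the muscle covariate (0.0096). Of 10 immediate early and heat shock genes 0 rose or fell, and Junb (0.77) rose adjusted over the list alone, 1 gene, with Egr1 at -0.48 and an adjusted p of 0.77 in camera, which called it lower without Hdac3 CKO replicate 1 (0.032) and with the muscle (0.038) and erythroid (0.0046) covariates. Of 13 hypoxia and glycolysis genes 0 rose or fell, also adjusted over the list alone, with Adm at -0.80 and Pdk1 at -0.26. Its median of 0.14 was above 0 while its mean of -0.0054 and camera's direction were below, with an adjusted p of 0.95, or 0.0084 and lower with the muscle covariate. Of 14 circadian clock genes 0 rose or fell, also adjusted over the list alone, with Nr1d1 at 0.34, Npas2 at 0.30 and an adjusted p of 0.51 in camera.

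The lists of PPAR targets and of fatty acid synthesis were called higher by camera with the preset correlation and not with an estimated one, and the adipocyte list was not called. Of 13 PPAR targets and fatty acid oxidation genes 1 rose and 0 fell, and 2 rose adjusted over the list alone. It was Angptl4, an inhibitor of lipoprotein lipase, at 2.19 ± 0.22, with Plin2 at 0.61, Plin5 at 0.54 and Pdk4 at 0.73. Camera gave an adjusted p of 0.0029, adjusted p = 0.51 with an estimated correlation. Of 13 fatty acid and sterol synthesis genes 2 rose and 0 fell, and 4 rose adjusted over the list alone. They were the desaturases Scd1 (0.73) and Scd2 (0.76), with Fasn at 0.58 and Srebf1 at 0.53, and camera gave an adjusted p of 0.0029, adjusted p = 0.22 with an estimated correlation. Angptl4 rose whichever library was left out, with an adjusted p of 0.0024 to 0.038 in edgeR's quasi-likelihood test. The synthesis genes that rose numbered 2 without Hdac3 CKO replicate 1, 1 without Hdac3 CKO replicate 2 and 0 without any other library. Of 11 adipocyte genes 0 rose or fell, also adjusted over the list alone, with Cidec at 1.67, Plin4 at 0.28 and an adjusted p of 0.26 in camera, which called it higher without wild type replicate 2 (0.0048).

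Among the patterning and signalling lists, camera with the preset correlation called only hindlimb identity. Across all tested genes, 1.18% passed. In fry's test for change in either direction, the adjusted p was 1.2e-04 for both the hedgehog and the Wnt list. It was 0.0015 for limb mesenchyme, 0.0053 for BMP and TGF-beta, 0.37 for hindlimb identity and 0.33 for Akt and Erk feedback. That test does not compare a list with other genes. Of 15 limb mesenchyme transcription factors 1 fell and 0 rose, and adjusted over the list alone 1 rose and 2 fell. It was Shox2, a regulator of proximal limb growth, at -1.10 ± 0.15, with Twist1 at 0.72 and an adjusted p of 0.077 in camera. It was called lower without wild type replicate 3 (0.011), without both cartilage-rich libraries (0.017), with no filter (0.040) and with the erythroid (0.031) and Y-linked (0.038) covariates. Of 5 hindlimb identity genes 0 rose or fell over all genes and 1, Tbx4 (-1.32), fell adjusted over the list alone. Pitx1 stood at -0.62, Hoxc11 at -0.26 and Hoxc9 at -0.16. Camera called this list lower with an adjusted p of 0.043, adjusted p = 0.61 with an estimated correlation. That call was lost without wild type replicate 2 (0.084), Hdac3 CKO replicate 2 (0.28) or Hdac3 CKO replicate 3 (0.27), and without both cartilage-rich libraries (0.12). It was also lost with the limb (0.069) and Y-linked (0.39) covariates. The limb covariate is the mean of this list less the level of the forelimb gene Tbx5, so the loss with it carries little weight. Hdac3 CKO replicate 1 had the highest hindlimb mean of the 6 libraries. Of 8 hedgehog pathway genes 1 rose and 0 fell, and 2 rose adjusted over the list alone, with Gli2 at 0.49. Its median of -0.01 differed in sign from its mean of 0.21 and camera's direction, which was higher, with an adjusted p of 0.58, or 0.014 with the erythroid covariate. Of 11 Wnt targets 1 fell, the Wnt inhibitor Wif1 (-0.86), and adjusted over the list alone 1 rose and 3 fell, with Dkk2 at -1.02 and an adjusted p of 0.38 in camera. Of 15 BMP and TGF-beta pathway genes 2 rose, Tgfbi (1.04) and Id3 (0.90), and adjusted over the list alone 2 rose and 1 fell, with an adjusted p of 0.37 in camera. Of 10 Akt and Erk phosphatases and feedback genes 0 rose or fell, also adjusted over the list alone, with Dusp4 at 0.49, Spry4 at 0.33 and an adjusted p of 0.69 in camera.

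Markers of other limb tissues mostly did not pass. Of 15 skeletal muscle genes 0 rose or fell, also adjusted over the list alone, with Des at 0.53, Tnni2 at 0.45, Atp2a1 at 0.44 and Myh3 at 0.33. Camera called the list higher with an adjusted p of 0.0029, adjusted p = 0.61 with an estimated correlation. The call was lost without Hdac3 CKO replicate 1 (0.11) and with the erythroid covariate (0.59), and the means of Hdac3 CKO replicates 2 and 3 lay within the wild type range. Of 7 tendon genes 1 rose, also adjusted over the list alone, the matrix protein gene Thbs4 (1.09), with Fmod at 0.50 and an adjusted p of 0.12 in camera, which called it higher without wild type replicate 1 (0.016) and with GC and length offsets (0.029). Of 9 endothelial genes 0 rose or fell, also adjusted over the list alone, with Eng at 0.44, Tie1 at 0.35 and an adjusted p of 0.078 in camera, which called it higher without wild type replicate 2 (0.021) or Hdac3 CKO replicate 3 (0.040) and with the limb (0.022) and Y-linked (0.040) covariates. Of 8 epidermis genes 0 rose or fell over all genes and 2 rose adjusted over the list alone, Trp63 (0.71) and Krt15 (2.55), with an adjusted p of 0.059 in camera. It was called higher without wild type replicate 1 (4.5e-04) or Hdac3 CKO replicate 1 (0.0028), with no filter (0.022) and with the muscle covariate (4.4e-04). Of 8 Schwann and nerve genes 0 rose or fell, also adjusted over the list alone, with Sox10 at 0.55 and S100b at -0.38. Its median and mean were both 0.07 and camera's direction was lower, with an adjusted p of 0.83. It was called higher with the erythroid covariate (0.020) and lower without both cartilage-rich libraries (0.040).

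Camera with the preset correlation called 14 of 34 lists, 0 were called with an estimated correlation, and fry called 5. In the other splits of the 6 libraries into 3 and 3, camera with the preset correlation called 6 to 15 lists and fry called 0.

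The libraries also differed in ways the genotypes do not name. Hdac3 CKO replicate 1 stood apart on the first principal component, which held 41.9% of the variance. It had the highest skeletal muscle mean, 11.3 on the log2 CPM scale against 10.5 to 10.8 in the others, and the forelimb gene Tbx5 stood at 2.13 CPM there against 6.22 to 9.53 in the others. Pitx1, a hindlimb gene, stood at 5.59 and 4.95 CPM in Hdac3 CKO replicates 2 and 3 and at 11.3 to 23.6 in the others. Among the sex-linked genes, Xist stood at 19.3 CPM in Hdac3 CKO replicate 3 against 700.1 to 2094 in the others, and 4 Y-linked genes summed to 132 CPM there against 1.71 to 5.60. Wild type replicate 3 and Hdac3 CKO replicate 3 held the most cartilage transcripts. Without both, edgeR's quasi-likelihood test called 0 genes at 2 libraries against 2, with 2309 at an unadjusted p under 0.05.

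**Figure D3:**
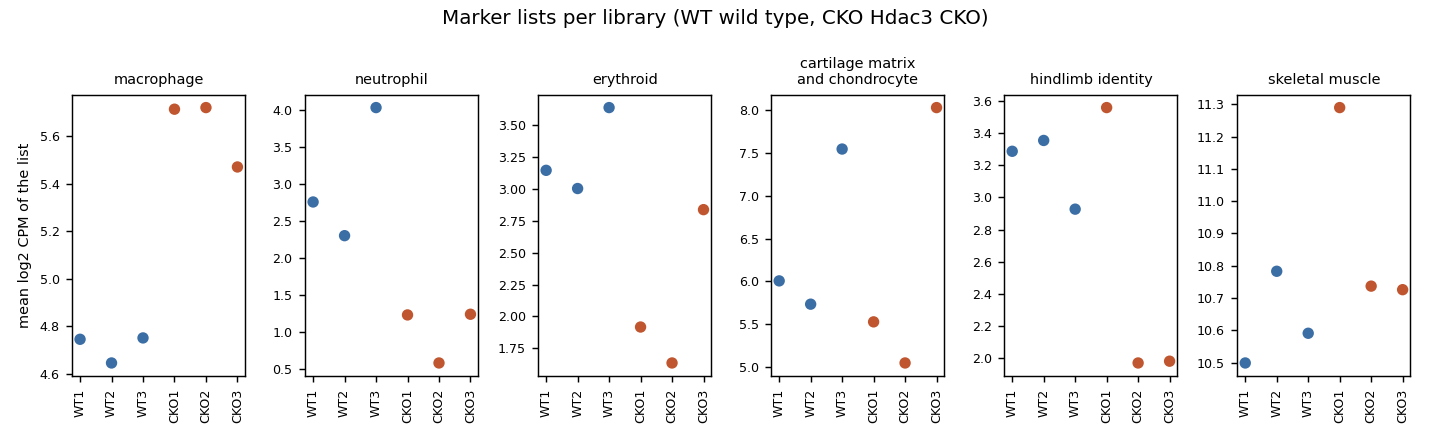
Mean log2 CPM of the members of 6 marker lists (vertical axes, 1 scale per panel) in each library, blue for wild type and orange for Hdac3 CKO. Macrophage and neutrophil means did not overlap between the genotypes, while cartilage, hindlimb and muscle means varied within them.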

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

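The 1.5-fold threshold, other tools and units, most covariates and leaving out libraries were chosen before the data were examined. The cartilage covariate, leaving out both cartilage-rich libraries, leaving out loci of ribosomal RNA type, GC and length offsets, and the list tests with limb and Y-linked covariates were chosen after the result was seen. No paired analysis was possible because the labels share no replicate numbers between the genotypes. All 238 genes that were tested under a setting kept their direction there, though a filter of at least 1 CPM left 222 of them and leaving out muscle, blood and sex-linked genes left 232. The count of calls, higher and lower, was 829, 455 and 374 with DESeq2, 157, 105 and 52 with limma-voom, 96, 37 and 59 with log2(RPKM + 1), and 140, 51 and 89 with log2(RPKM + 0.1). It was 12, 9 and 3 when a change beyond 1.5-fold was tested, and 178, 58 and 120 with library totals alone. With covariates it was 86, 64 and 22 (muscle), 37, 37 and 0 (erythroid), 0, 0 and 0 (neutrophil), 111, 74 and 37 (Y-linked), 1851, 779 and 1072 (limb) and 142, 72 and 70 (cartilage). It was 344, 181 and 163 with GC and length offsets, and 0, 0 and 0 without both cartilage-rich libraries, where fewer libraries remained. With the neutrophil and erythroid covariates 1271 and 907 genes had an unadjusted p under 0.05 in edgeR. Neither marker mean overlaps between the genotypes, which leaves these tests, that of Hdac3 included, little to separate them by. Leaving out 1 library gave 23 to 175 calls, 11 to about 1.2e+02 higher and 10 to 59 lower. They were 23 without wild type replicate 1, 35 without wild type replicate 2, 105 without wild type replicate 3 and 46 without Hdac3 CKO replicate 3, and the lower genes were 59 without Hdac3 CKO replicate 1 and 58 without Hdac3 CKO replicate 2.

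The log2 fold change of Hdac3 lay between -0.89 and -0.61 over 28 alternatives and passed in 17, with adjusted p from 2.9e-04 to 0.837. It did not pass with log2(RPKM + 1) at -0.74, or with the erythroid (-0.74), neutrophil (-0.61), Y-linked (-0.67) and cartilage (-0.71) covariates, or without both cartilage-rich libraries (-0.65). Without 1 library it ranged from -0.76 to -0.67. The number of lists called was 0 with an estimated correlation, 5 with fry and 12 to 19 otherwise. Of 3168 values of the 114 genes the naming rule selects under alternatives, 2535 had the same call, 498 lost it, 115 gained it and 20 turned direction, none of the last past the threshold in either setting. With the erythroid covariate Sox9 turned to 0.73, S100b to 0.70 and Myh3 to -0.048. With the neutrophil covariate Sox9 turned to 0.49, S100b to 0.66, Mepe to 0.23, Hoxc9 to 0.48 and Krt15 to -0.14. With the Y-linked covariate Col2a1 turned to -1.54, Col10a1 to -0.22 and Hoxc9 to 0.050. Col2a1 stood at -0.0023 with log2(RPKM + 0.1) and at -0.31 without both cartilage-rich libraries, and Hoxc9 at 0.12 there. Leaving out 1 library gave Col2a1 -1.76 to 2.36, Col10a1 -0.41 to 1.25, Hoxc11 -1.33 to 0.077 and Hoxc9 -0.68 to 0.076. The skeletal muscle list had a signed adjusted p of -0.886 with the muscle covariate, which is built from that list. For the other changes the cause was not tested. At this depth and with 3 libraries per genotype, the simulated test called 51.0% of 2-fold changes.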

Other observations

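The fits with limb, Y-linked, neutrophil and muscle covariates were planned before the data were examined, but the tests that read them by the ratio or median they leave, and those of the 2 marker medians and of the splits, were chosen only after the result was seen. The tests on other marrow markers, other ATF4 targets, other chaperones and the genes that follow the limb covariate were written before their values were seen. The ATF4 and chaperone sets were nevertheless drawn up knowing which genes had been called, since called genes were left out of them. The genes in the next paragraph were chosen after their values were seen.

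Some genes outside the fixed lists passed the test, and no enrichment was tested for them as a group. Fibronectin (Fn1) rose by 1.13 ± 0.15, the collagen chaperone Serpinh1 by 1.22 ± 0.15, the collagen prolyl hydroxylases P4ha1 and P4ha2 by 0.95 and 0.75, Col5a1 by 1.01, Bgn by 0.92, Tnc by 0.84 and Mgp, an inhibitor of calcification, by 1.44. Adamts15, Adamts16, Adamts18 and Adamts19 stood at -0.95, -2.15, -1.97 and -1.90, and all 4 passed edgeR's quasi-likelihood test, while Adamts4, of the fixed protease list, rose by 0.75. The secreted Wnt antagonist Sfrp4 rose by 1.92 ± 0.21, while Dpp4 (-2.08) and Pi16 (-1.25), both markers of connective tissue fibroblasts, fell.

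The 238 calls between the genotypes were set against the make-up of the libraries. The real split gave 238 genes and the highest of the other 9 splits gave 0, 1 of 10 splits being as large, and 10 splits are too few for a share under 0.05. With the limb covariate the called genes kept a median of 1.02 of their log2 change, with 237 of 238 still called, and with the Y-linked covariate a median of 1.03, with 95 still called at 3 residual degrees of freedom. Only Hdac3 CKO replicate 3 stood apart on the Y-linked covariate (7.05 against 0.78 to 2.49), so that ratio alone could hardly fall. Hdac3 CKO replicates 1 and 2 had high Xist (700.1 and 1425 CPM), as had wild type. They lay on the same side of wild type as replicate 3 in all 238 genes, but the test that called these genes favours such agreement. Without replicate 3, every remaining library had high Xist, and 46 genes were called, 44 of them among the 238. That argues against sex as the source of those 44 calls. The limb ratio alone decides nothing, because no gene followed that covariate past the threshold and its mean differs little between the genotypes. On it the wild type libraries (0.22 to 0.64) lay between Hdac3 CKO replicates 2 and 3 (-1.05 and -1.28) and replicate 1 (2.44). A gene set by this limb measure would place replicate 1 and replicates 2 and 3 on opposite sides of wild type. All 238 genes had the Hdac3 CKO libraries on the same side of wild type, without overlap, but the test that called them favours such genes. A gene set by this limb measure alone would hardly be called, so the agreement is no separate evidence against uneven limbs. Limb differences that the markers miss stay open. With the neutrophil covariate the median was 1.08, the 10th and 90th percentiles were 0.512 and 1.43, and 0 genes were called. Because that covariate does not overlap between the genotypes, a lower share of marrow cells cannot be told apart from genotype for these genes. The limb covariate raised the count of calls to 1851, but 0% of skeletal muscle genes, and 0 of 20210 genes in all, followed the covariate past the threshold, with 4209 at an unadjusted p under 0.05 in edgeR. The rule written beforehand would have read 0% as showing that limb identity alone sets this covariate. But hindlimb identity genes, from which the covariate is partly built, did not pass it either, with a median slope of 0.52. The test therefore decided nothing and the reason for the higher count stays open.

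The splits bear on the gene lists as well. Camera with the preset correlation called 14 lists in the real split and up to 15 in another, 2 of 10 splits being as large, and 10 splits are too few for a share under 0.05.

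Of the macrophage markers 5 of 9 rose, while 4 of 8 neutrophil, 1 of 8 B lymphoid and 2 of 10 erythroid markers fell, and the adjusted p of these lists was 0.075, 0.41, 0.41 and 0.22 in camera with an estimated correlation. The macrophage median lay 3.47 above the neutrophil median on the log2 scale, which argues against 1 common change in all blood and marrow cells. With the muscle covariate the macrophage median was 0.91, against 0.98 without it. Only Hdac3 CKO replicate 1 stood apart on that covariate, so this median alone could hardly fall. Muscle means of Hdac3 CKO replicates 2 and 3 (both 10.7 log2 CPM) lay within the wild type range (10.5 to 10.8). Their macrophage means (5.7 and 5.5) lay above the wild type range (4.6 to 4.8). That argues against muscle left on the bones as the source of the higher macrophage values in replicates 2 and 3. Soft tissue without muscle was not tested. Whether less marrow in the Hdac3 CKO bones may explain the lower markers was tested on 15 measured marrow genes outside the lists. Their median was -0.31 and 12 of 15 were lower. Of the 15, 5 had an unadjusted p under 0.05 in edgeR, all of them lower, and 0 fell past the threshold. The largest median of another split was 0.37 in size. By this median, less marrow cannot be told apart from other groupings, and whether it would arise in the animal or in dissection was not tested.

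Chac1 (2.74), Trib3 (1.57), Atf5 (1.59), Fgf21 (3.51), Gdf15 (2.08), Ddit4 (1.15) and Nupr1 (1.68) rose, and as a hypothesis they may reflect an amino acid response driven by ATF4. The median of 26 other ATF4 targets was 0.38, with 25 higher, against at most 0.20 in size in another split, and 95% of 10000 random lists matched on expression lay between -0.09 and 0.17. The median of 15 other chaperones of the endoplasmic reticulum was 0.29, with 14 higher, against at most 0.21 in another split and a random range of -0.05 to 0.28, so a wider unfolded protein response also stays open. The random lists drew genes independently of each other and could hold called genes, so their ranges leave out any joint movement of the genes in a set. For both sets 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. Genes already called were left out of both sets, and 13 of the ATF4 targets and 6 of the chaperones had an unadjusted p under 0.05 in edgeR. The fixed stress list, which holds Chac1 and Trib3, had an adjusted p = 0.15 with an estimated correlation in camera, while with the preset correlation it was called higher with GC and length offsets (adjusted p 3.0e-08) and with the muscle (1.0e-06), limb (3.2e-05), Y-linked (5.6e-06) and cartilage (5.7e-07) covariates, and no technical explanation was tested on the other genes of this pattern as a set.

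Y-linked genes summed to 298 counts in wild type replicate 1 and 188 in Hdac3 CKO replicate 2, against 71 to 123 in the other libraries with high Xist and 5686 in Hdac3 CKO replicate 3. The overlapping loci Yam1 and AY036118 held 8.07% to 12.8% of the counts of each library, and the mitochondrial genes held 0 counts in every library.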
